A study of Mus musculus with 2 samples.

How the data were processed

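Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 trimethylated at lysine 36 (H3K36me3), a modification laid down along the bodies of transcribed genes, in the hindbrain of mice on postnatal day 0. The labels describe 1 group of 2 biological replicates, each a pool of tissue from male and female pups of a B6N strain. Replicate 1 came from 15 mice, and replicate 2 combined 2 technical replicates. There was no second group, so no comparison between conditions could be made, and the replicates were compared with each other.

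The authors deposited 4 peak lists on the mouse assembly mm10. Per the file headers, 1 list was made from each replicate's alignment together with a control alignment, another from the pooled alignments of both replicates, and the last, called replicated, from the replicate lists and the pooled list. The aligner, the peak caller, their versions, the read depth and the rule behind the replicated list are not given in the sources used here. The depth is therefore unknown, and no counting error can be attached to a single peak. The peak score deposited by the authors is a display value and was not used. The ratio deposited by the authors for each peak is its linear fold enrichment over control, and it was used to describe, rank or filter peaks within a list and, as planned, for a rank correlation of the replicate lists across peaks. The deposited −log10 p-value and −log10 q-value of each peak served as filters, and the lowest deposited −log10 p was 2.02 in each replicate list. Every replicated peak was also a row of the pooled list.

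Peaks on chromosomes 1 to 19, X and Y were analysed. Peaks on other sequences numbered 6 in replicate 1, 7 in replicate 2 and 4 in the replicated list, and were left out of all comparisons. Genes and exons were taken from GENCODE M21, which uses the same assembly. Chromosome lengths were checked and no peak ran past the end of a chromosome. A gene body ran from the annotated start to the annotated end, and exons came from transcripts tagged basic. The covered share of a gene is the percent of its body lying under peaks. ChIP-seq carries no strand, so coverage of overlapping genes cannot be separated. A protein-coding gene with a body of at least 1 kb was called marked when at least 10% of the body was covered in each of the replicate lists.

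Overlap of the replicates was the share of peaks with at least 50% of their bases in the other list, together with the Jaccard index in bases, and both were also computed with bedtools 2.31.1, which gave the same values. Chance overlap and chance genic share came from 200 circular shifts of the peaks within each chromosome, and the one-sided permutation p has a smallest possible value of 0.00498. Position was measured in 10 equal bins of the body and 5 kb flanks, over marked genes of at least 5 kb. Gene lists for cell types, regional identity, tissues that should be silent, chromatin machinery and gene families, 32 in all, were fixed before the data were examined, as were the rule for naming genes and all tests and alternatives except those said to have been chosen later. Each list's median and mean covered share was placed among 10000 random lists of as many protein-coding genes matched on length decile. That percentile describes these libraries and is not a p-value, since genes are not replicates. Intergenic peaks were replicated peaks more than 5 kb from any annotated gene, merged when within 5 kb of each other.

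Named genes were the 10 protein-coding genes of at least 5 kb with the highest mean covered share among those at 10% or more in both replicates, the 10 with the most bases under replicated peaks, the 2 highest and the lowest member of each list, the 5 intergenic domains with the most covered bases, and the 5 genes marked in a single replicate with the largest difference between replicates. Means are over the replicates, with SD and n = 2. Wilson or exact 95% intervals of shares of peaks cover counting error only.

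Alternatives were a −log10 q of at least 2, the pooled or the replicated list in place of the replicate lists, lists of equal length, overlaps of 1 base or 80%, gene coverage minimums of 5% and 20%, protein-coding genes alone, no length minimum, genes overlapping no other gene, means in place of medians, an intergenic distance of 20 kb, a merging distance of 1 kb, and each replicate left out in turn. The closing section gives their effect. The scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data. Covered bases equalled a base-by-base count in 300 of 300 queries, and a planted 59.1% of shared peaks was recovered as 59.1%. Of 200 random lists of 15 genes drawn from the 21221 protein-coding genes, 5.5% fell outside the central 95% by mean. All 100 lists raised by 20 percentage points passed above the central 95% by median. So large a rise is easily passed, and neither smaller rises nor the rate of random lists outside by median were checked.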

Results

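H3K36me3 peaks were mapped in hindbrain tissue of newborn mice from 2 biological replicates, each a pool of both sexes. Replicate 1 had 115873 peaks with a median width of 279 bases and a median fold over control of 3.26, and covered 40.7 Mb or 1.49% of the genome. Replicate 2 had 151639 peaks with a median width of 362 bases and a median fold of 3.49, and covered 77.0 Mb or 2.82%. The pooled list held 158052 peaks over 81.0 Mb. The replicated list held 85762 peaks over 61.3 Mb, with a median width of 538 bases. Fold and significance values are the authors' own. In replicate 1, 47.7% of peaks reached a −log10 q of 2, against 87.5% in replicate 2. The number of reads behind each list is unknown.

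The first comparison asked how far the replicates marked the same places. Across 21221 protein-coding genes, the percent of the gene body under peaks followed the same order in both replicates, with a Spearman rho of 0.93 and a Pearson r of 0.945. Genes are not independent replicates, so no p is given. Peak by peak the overlap was looser. Of replicate 1 peaks, 65.5% had at least 50% of their bases in replicate 2 peaks (95% Wilson interval 65.3 to 65.8), while 28.7% of the more numerous and wider replicate 2 peaks met the same condition in replicate 1 (28.5 to 28.96). The latter share ranged from 10.3% when 80% of the peak was asked for to 48.3% with 1 base. The Jaccard index was 0.307, against a mean of 0.0116 and a highest value of 0.0179 in 200 circular shifts (one-sided permutation p = 0.00498, the smallest they can give). Among peaks called in both lists, the order of peak strength was shared only in part. Across 65954 replicated peaks overlapping a peak in both lists, the fold in replicate 1 and in replicate 2 had a Spearman rho of 0.331. Places below the limit of calling do not enter, which narrows the range of folds and can lower rho. The replicated list kept 54.3% of pooled peaks, rising from 15.8% (exact 95% interval 15.5 to 16.2) in the quintile of lowest pooled fold to 97.7% (97.53 to 97.87) in the highest quintile. Of pooled peaks overlapping both replicate lists, 97.8% were in the replicated list, as were 28.2% of those overlapping replicate 2 alone and 17.4% of those overlapping replicate 1 alone.

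The next question was which genes carried the mark. Nearly all of it lay inside genes: 96.3% ± 0.00525 (SD, n = 2) of peak bases fell in annotated gene bodies, which make up 44.8% of the genome, a 2.15-fold excess. Shifted peaks gave at most 1.15-fold for replicate 1 and 1.13-fold for replicate 2 (one-sided permutation p = 0.00498 for each). In all, 4859 of 21221 protein-coding genes (22.9%) were marked in both replicates, and 9424 (44.4%) had no peak base in either. With a coverage minimum of 20% the count was 2499, and with a −log10 q of at least 2 it was 3131. Replicate 1 alone would mark 4922 genes and replicate 2 alone 7052. Only 63 genes were marked in replicate 1 and not in replicate 2, against 2193 in the other direction. Among long intergenic noncoding RNA genes that overlap no other gene, 7 of 3663 were marked.

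Among protein-coding genes of at least 5 kb, the gene covered over the largest part of its body was Fasn, the fatty acid synthase gene (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547, mm10), at 78.0% ± 9.91 (SD, n = 2) of its 18.7 kb. The proline-rich coiled-coil gene Prrc2a followed at 73.8% ± 3.03. Prpf8 (chromosome 11, 75486816 to 75509449) and Snrnp200 (chromosome 2, 127208386 to 127240451), which encode core proteins of the spliceosome, reached 73.3% ± 9.77 and 71.7% ± 12.1. Dync1h1, the heavy chain of cytoplasmic dynein (chromosome 12, 110601452 to 110666945), reached 71.6% ± 12.8 of 65.5 kb. The remaining 5 of the highest 10 were the ataxin-2-like gene Atxn2l at 71.3% ± 11.7, the cell polarity gene Scrib at 70.7% ± 14.5, Hnrnpul1, which encodes a ribonucleoprotein, at 70.3% ± 16.1, the deubiquitinase gene Bap1 at 70.1% ± 4.10 and the translation initiation factor gene Eif3d at 70.1% ± 9.82. Prrc2a, Dync1h1, Scrib and Eif3d overlap another annotated gene, so part of their coverage may belong to it.

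By bases under replicated peaks, the leading loci were large genes. The ubiquitin ligase gene Ubr4 (chromosome 4, 139352609 to 139489588) carried 110.5 kb, with 67.6% ± 15.7 of its body covered. Wdfy3, an autophagy scaffold, carried 88.0 kb, the lipid transport gene Vps13d 85.8 kb, and the cytoskeletal linker genes Macf1 and Dst carried 85.2 kb and 70.4 kb. The ligase genes Hectd4 and Herc2 carried 79.7 kb and 70.1 kb, and Trrap, a subunit of histone acetyltransferase complexes, carried 73.3 kb over 66.7% ± 16.3 of its body. The annotated spans of Gm20388 (341.2 kb under replicated peaks) and Fgfr2 (94.9 kb) reach over 4435 kb and 2961 kb and take in other genes, so their sums do not belong to a single gene. Of the others, all but Vps13d overlap another annotated gene to some extent, and part of their sums may belong to it.

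Along the gene, coverage was lowest around the start and highest near the end. Over 4512 marked genes of at least 5 kb, the kilobase before the start was covered at 0.828% ± 0.338 (SD, n = 2), bin 1 of the 10 body bins at 3.70% ± 1.73, bin 5 at 28.96% ± 11.7 and bin 9 at 43.0% ± 15.3. Past the end, coverage fell to 27.4% ± 11.3 in the first kilobase and 10.4% ± 4.07 in kilobase 5. The last 25% of the body was covered 4.22 ± 0.363 times as densely as the first 25%, with 4.47 in replicate 1 and 3.96 in replicate 2. The SDs of the covered percents are large because replicate 2 was covered more densely throughout, and the ratio, taken within a replicate, varied less.

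**Figure D1:**
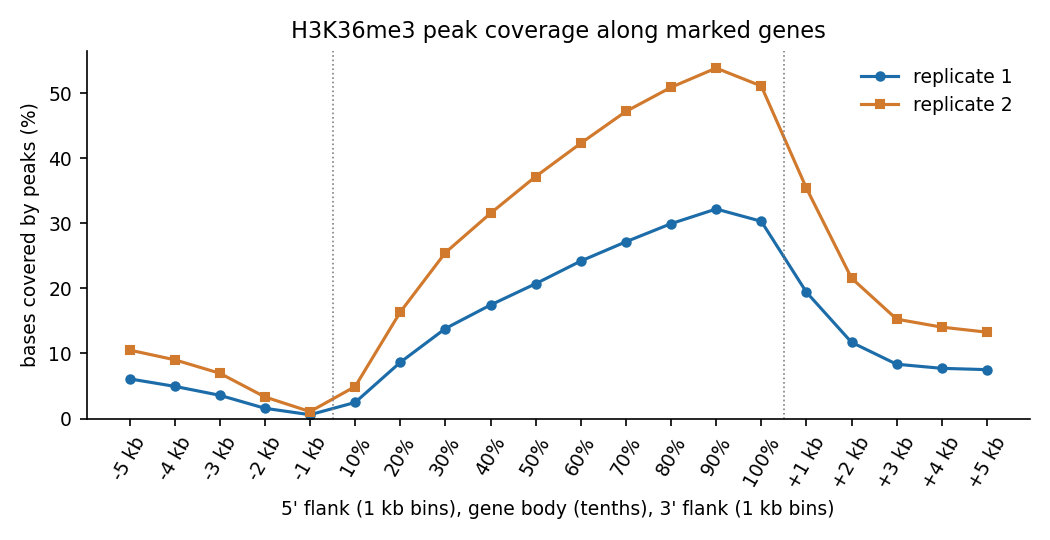
Percent of bases covered by H3K36me3 peaks (vertical axis) in 1 kb bins of the flanks and in 10 equal bins of the gene body (horizontal axis), over 4512 marked genes, with points and a line for each replicate. Both replicates are lowest in the kilobase before the start (0.588% and 1.07%) and highest in body bin 9 (32.2% and 53.9%).

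Within marked genes, exons were covered at 43.6% ± 13.6 (SD, n = 2) and introns at 26.0% ± 10.4, a ratio of 1.71 ± 0.163. First exons were covered at 4.89% ± 1.46 and later exons at 47.8% ± 14.9, a ratio of 9.74 ± 0.13. Coverage also rises towards the 3′ end. In the later part of the body alone the ratio of exons to introns was 1.35 and that of later to first exons 1.501, alternatives chosen after seeing the data. First exons were exon 1 of any basic transcript, and only those reaching into the later part count there. They are a different set, covered at 26.1% in replicate 1 and 38.5% in replicate 2. The 1.501 therefore cannot say how much of the 9.74 is due to position.

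The lists of genes were then compared with random lists matched on length. Of the 32 lists, 4 had a median above the central 95% of the random lists in both replicates. The first was the list of constitutively expressed genes, where 19 of 24 members were marked and the median covered share was 34.3% ± 10.7 (SD, n = 2), at the 100th percentile in each replicate. Its highest members were the chaperonin gene Cct2 at 61.0% ± 23.9 and the ribosomal protein gene Rps3 at 58.8% ± 10.6. Its lowest was the X-linked Hprt, a purine salvage gene, at 2.69% ± 3.80. Among the cytosolic ribosomal protein genes, which share Rps3 and Rpl3 with that list, 45 of 78 were marked with a median of 23.1% ± 11.6 (100th percentile in each). Rps5 was covered at 58.2% ± 12.7, and Rps27l had no peak base. Many ribosomal protein genes have near-identical pseudogenes with which reads can be shared, so their values are uncertain.

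Genes for writers, erasers and readers of H3K36 methylation were themselves covered, with 16 of 23 marked and a median of 22.5% ± 7.88 (100th percentile in each replicate). Setd2, the main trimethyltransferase of H3K36, was covered at 22.6% ± 8.94 and the dimethyltransferase gene Nsd1 at 31.5% ± 14.1; both are named for their function and fell outside the rule for naming genes, so they were chosen after their values were seen. The demethylase gene Kdm4a was highest at 60.8% ± 15.4, followed by Supt6, an elongation factor that binds polymerase, at 54.0% ± 14.1, while Phf19 was lowest at 0.733% ± 1.04. The fourth list held zinc finger genes, whose products mostly bind DNA. Here 170 of 365 were marked, with a median of 13.04% ± 5.36 (100th percentile in each). Zfp869 reached 74.5% ± 21.6 and Zfp606 64.8% ± 16.0, while Zfp995 had no peak base and 73 of the 365 had none.

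Genes of dividing cells were covered but stayed within the central 95% of the random lists. Of 17 members, 7 were marked, with a median of 14.6% ± 7.53 (96.0th and 96.9th percentile). The maintenance methyltransferase gene Dnmt1 was covered at 53.0% ± 12.3 and the replication licensing gene Mcm4 at 42.4% ± 15.4, while Ccnb1 had no peak base.

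The pan-neuronal, glutamatergic, GABA and glycine, cerebellar granule cell, Purkinje cell, astrocyte and radial glia, and oligodendrocyte lists held 0 to 2 marked genes each. The random lists were scored within each replicate, a looser condition than marked, which asks for both replicates. Averaged over the replicates, a median of 16.7% to 33.3% of their genes was covered at 10% or more. Scored in the same way, none of these lists had a share below the central 95% of the random lists in both replicates. In the pan-neuronal list all 20 members had a peak base, but only Elavl3 (17.4% ± 6.31), which encodes a neuronal RNA-binding protein, and Tubb3 (15.9% ± 5.45), a neuronal tubulin, were marked, and Nrxn3, 1612 kb long, was covered at 0.134% ± 0.0336. The list median of 4.34% ± 2.64 lay at the 95.8th and 96.8th percentile, close to the percentiles of the list of dividing cells, while the list mean of 5.67% ± 2.75 lay near that of matched random lists at 5.60%. In the glutamatergic list Grin1, a subunit of the NMDA receptor, was marked at 19.4% ± 3.55, Gls was at 4.01% ± 0.536 and Tlx3 had no peak base. In the list for GABA and glycine, the transporter gene Slc6a1 was marked at 22.2% ± 14.0, Lhx1 was at 3.32% ± 0.887 and Slc32a1 had no peak base. In the cerebellar granule cell list the Hedgehog receptor gene Ptch1 was marked at 31.5% ± 8.30, Mycn was at 15.4% ± 15.6 and not marked in replicate 1, and Neurod1 had no peak base. No Purkinje cell gene was marked. Pcp2 was at 5.40% ± 7.64, Itpr1 at 1.85% ± 1.02 and Skor2 at 0. In the astrocyte and radial glia list the glutamine synthetase gene Glul was marked at 42.1% ± 6.93 and the intermediate filament gene Vim at 21.3% ± 5.27, while Sox2 had no peak base. In the oligodendrocyte lineage the myelin enzyme gene Cnp was marked at 47.9% ± 19.8, Myrf was at 5.15% ± 1.12 and Sox10 had no peak base.

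Transcription factor genes of regional identity had almost no coverage. None of 15 anterior Hox genes, among them Hoxa1, Hoxa2 and Hoxd4, and none of 16 posterior Hox genes, among them Hoxa10, Hoxa11 and Hoxd9, had a single peak base in either replicate. Of 14 factors of hindbrain and midbrain, 11 had none, with Irx1 highest at 1.85% ± 2.62, Pax2 at 0.271% ± 0.383 and Pou4f1 at 0. Of 19 forebrain factors, 17 had none, with Bcl11b at 0.42% ± 0.228, Satb2 at 0.0528% ± 0.0747 and Tbr1 at 0. The monoaminergic list was led by Slc18a2 at 0.876% ± 1.24 and Maoa at 0.577% ± 0.274, with Tph2 at 0, and the 9 cholinergic motor genes, including Chat, Ache and Slc5a7, had no peak base.

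Genes of cell types that are rare in the tissue or of other organs were likewise little covered. No gene of the microglial and immune list was marked, with Hexb at 13.6% ± 9.10, Cx3cr1 at 11.3% ± 2.60 and Tyrobp at 0. The vascular and meningeal list reached 0.937% ± 0.30 in Col1a2, 0.244% ± 0.345 in Pdgfrb and 0 in Tie1. The choroid plexus list reached 0.441% ± 0.186 in Trpm3 and 0.31% ± 0.0415 in Slc4a5, with Ttr at 0. The erythroid list reached 2.19% ± 0.982 in Alas2 and 1.08% ± 0.228 in Epb42, with Slc4a1 at 0. Among genes of liver, muscle and germ cells the highest values were 1.49% ± 2.10 in F2, 2.45% ± 1.67 in Ttn and 2.23% ± 3.15 in Sycp3, whereas Ahsg, Tdo2, Tnni2 and Tex14 had no peak base, Tnnt3 was at 0.568% ± 0.803 and Mov10l1 at 0.135% ± 0.191. The keratinocyte genes, including Dsg1a, Dsg3 and Tgm1, and the 19 clustered histone genes, including Hist1h1c, Hist1h1d and Hist4h4, had none. Of 1069 olfactory receptor genes 1068 had no peak base, the exception being Olfr943 at 0.374% ± 0.529, and none of 274 vomeronasal receptor genes had any. By mean covered share, 16 of the 32 lists fell below the 2.5th percentile in both replicates, among them the Hox, regional factor, monoaminergic, cholinergic, liver, muscle and receptor lists.

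Imprinted genes were mixed. Of 29 members 4 were marked, Igf2r at 26.3% ± 10.8, Impact at 20.4% ± 9.76, Nnat at 17.5% ± 6.16 and the noncoding Meg3 at 16.8% ± 6.63, while Peg10 had no peak base. Nnat and Meg3 are given to complete the count and were named after their values were seen. Among 57 clustered protocadherin genes 1 was marked, Pcdhgc5 at 14.8% ± 6.28, followed by Pcdhgc4 at 14.3% ± 8.02, with Pcdhb9 at 0. All 16 very long synaptic genes had some peak bases and none was marked, from Dscam at 1.86% ± 1.02 and Auts2 at 1.54% ± 0.871 to Cntnap2, 2245 kb long, at 0.012% ± 0.00476.

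Many genes of the lists share their annotated body with another gene, and part of their coverage may belong to it. Among those named at 10% or more, this holds for Rps3, Setd2, Nsd1, Kdm4a, Supt6, Dnmt1, Elavl3, Tubb3, Grin1, Ptch1, Glul, Cnp, Hexb, Cx3cr1, Igf2r, Impact, Nnat, Meg3, Pcdhgc5 and Pcdhgc4, and not for Cct2, Rps5, Zfp869, Zfp606, Mcm4, Slc6a1, Mycn and Vim.

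**Figure D2:**
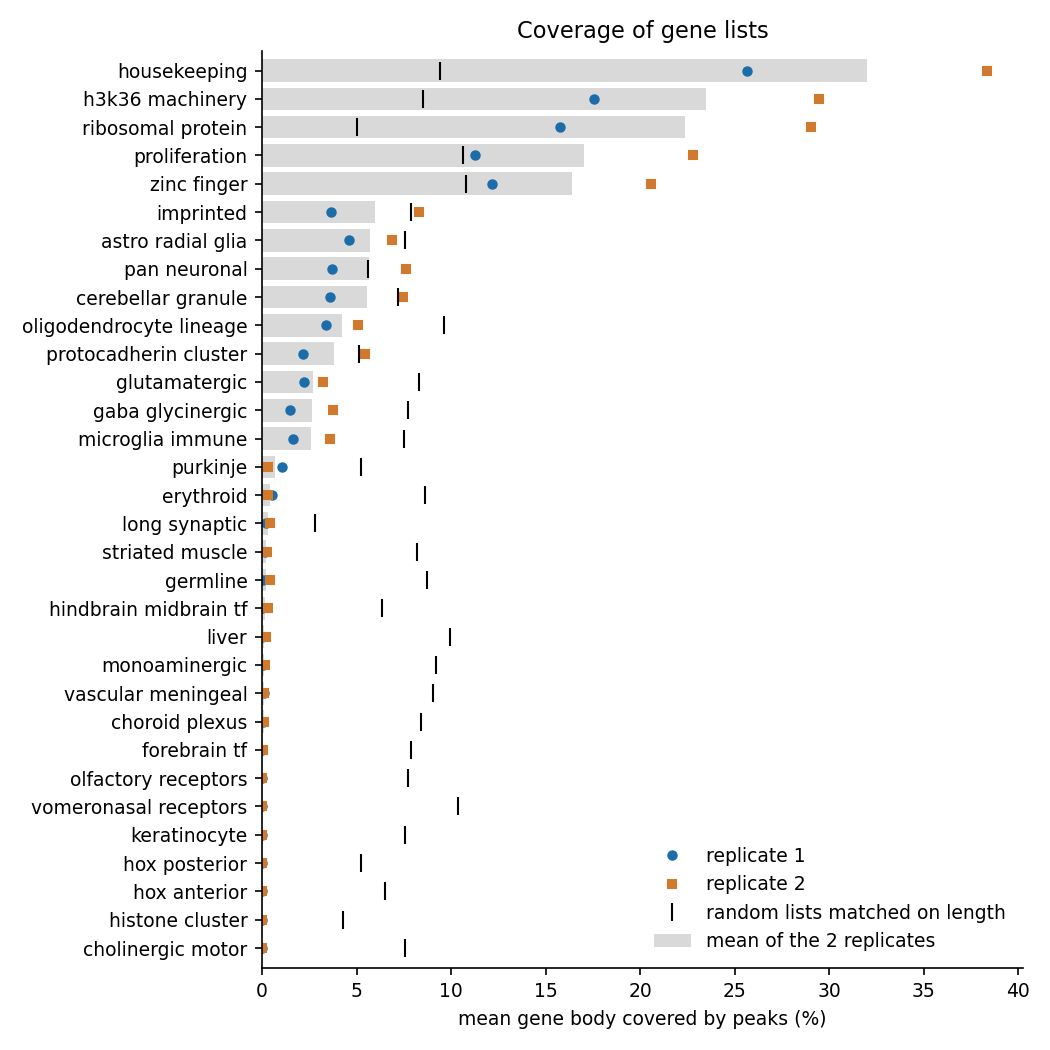
Mean percent of gene body covered by peaks (horizontal axis) for each of the 32 gene lists (vertical axis). Bars are means of the replicates, points the single replicates, and black ticks the median over random lists matched on length; the H3K36 list stands at 23.5% against 8.54% for its random lists, and the anterior Hox list at 0 against 6.53%.

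The share of marked genes depended on gene length. It was 10.1% for bodies of 1 to 5 kb, 27.5% for 5 to 20 kb, 33.6% for 20 to 50 kb, 21.2% for 50 to 100 kb, 8.90% for 100 to 200 kb and 1.40% above 200 kb, where 14 of 998 genes were marked. The share at 5 to 20 kb was 19.6 times that above 200 kb, 54.6 times with a coverage minimum of 20%, and 12.4 times in the replicated list. By replicate 1 alone it was 19.8 times and by replicate 2 alone 6.58 times. A minimum set as a percent of the body asks more bases of a longer gene, so these shares describe dense coverage and not presence of the mark.

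**Figure D3:**
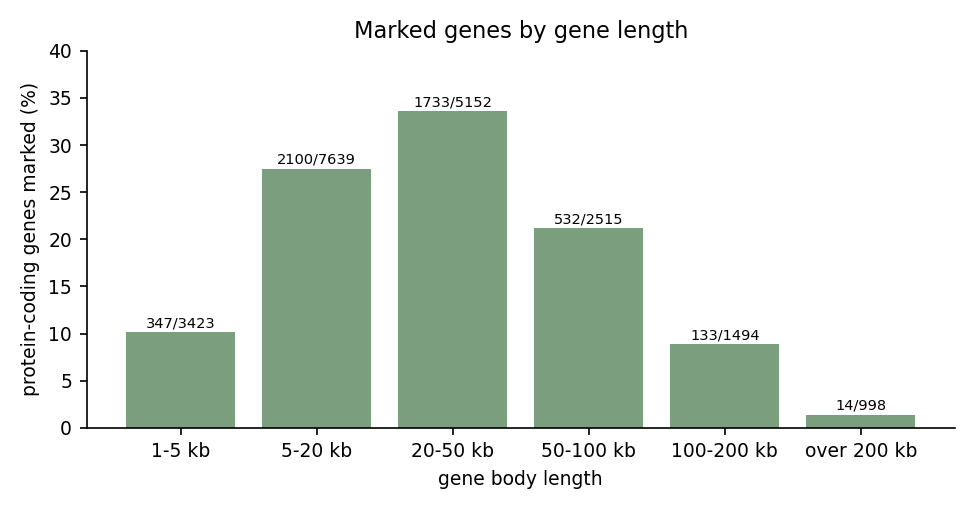
Percent of protein-coding genes marked in both replicates (vertical axis) by gene body length (horizontal axis), with marked and total genes above each bar. The share is highest at 20 to 50 kb (33.6%) and lowest above 200 kb (1.40%).

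Chromosomes differed in the same measure, and the X stood apart from the autosomes. On the X 15 of 877 protein-coding genes (1.71%) were marked, against 4844 of 20181 (24.0%) on the autosomes, a ratio of 0.0713. The ratio was 0.075 by replicate 1 alone and 0.164 by replicate 2 alone, 0.115 in the replicated list and 0.0221 with a −log10 q of at least 2. The gap was smaller for genes with any peak base, which made up 23.3% of X-linked and 52.5% of autosomal genes in replicate 1, and 27.3% and 54.5% in replicate 2. The autosomes ranged from 16.6% on chromosome 14 to 31.8% on chromosome 8, and none of 163 genes on the Y was marked. In covered bases the X stood at 0.174% ± 0.0832 (SD, n = 2), chromosome 3, the lowest autosome, at 1.51% ± 0.698 and chromosome 11, the highest, at 3.98% ± 1.67. The pools held both sexes in proportions not given, and no test of this ratio was planned.

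**Figure D4:**
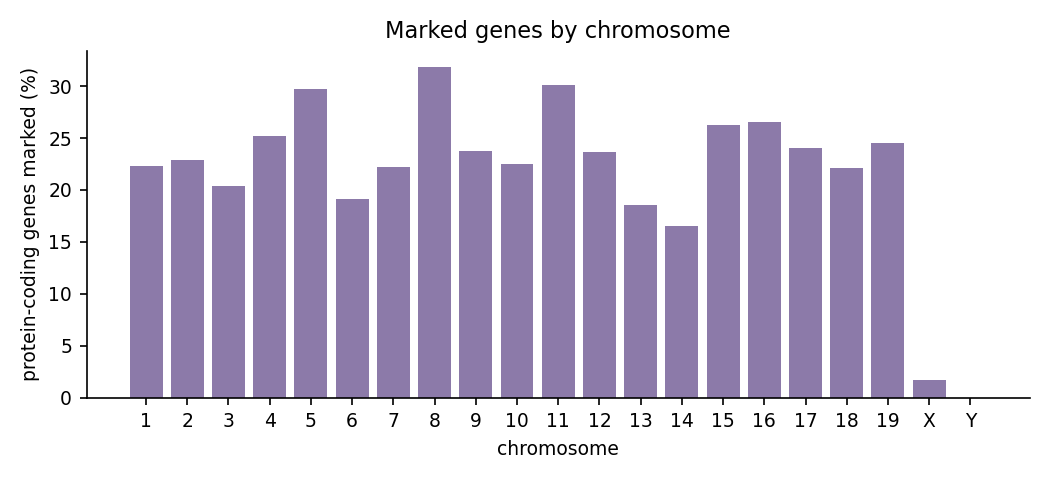
Percent of protein-coding genes marked in both replicates (vertical axis) on each chromosome (horizontal axis). The bar for the X stands at 1.71% and that for the Y at 0, with all autosomes between 16.6% and 31.8%.

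Outside genes the mark was sparse. More than 5 kb from any annotated gene lay 86 replicated peaks (0.10% of the list), which merged into 63 domains covering 35705 bases, and 42 of the domains had bases in both replicate lists. The domain with the most covered bases lay on chromosome 4 (119269719 to 119272140), 5.84 kb downstream of Ybx1, with 2.05 kb under peaks. The next stood on chromosome 5 (104582294 to 104586394) with 1.66 kb, 59.7 kb downstream of BC005561, and on chromosome 7 (28193341 to 28198899) with 1.57 kb, 6.05 kb downstream of Dyrk1b. The others were on chromosome 2 (151520499 to 151527362), with 1.38 kb, 9.08 kb downstream of Nsfl1c, and on chromosome 14 (73601314 to 73602810), with 1.20 kb, 5.17 kb downstream of Sucla2. The distances given are to the nearest protein-coding gene. The marked long intergenic noncoding RNA gene D930016D06Rik (104525735 to 104554207) lies nearer the domain on chromosome 5 than BC005561 does. Beyond 20 kb from a gene, 3 domains remained.

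The genes that differed most between the replicates among those marked in a single replicate were short, and each was covered in replicate 2. Tmem86b went from 6.41% in replicate 1 to 60.8% in replicate 2, Mfsd5 from 0 to 53.2%, Rpl21 from 4.95% to 57.6%, Gm6588 from 0 to 49.0% and 1700020D05Rik from 0 to 48.8%. With 1 value per replicate these differences cannot be tested. All but Mfsd5 overlap another annotated gene, and part of their coverage may belong to it. Gm6588 and 1700020D05Rik had no base under replicated peaks.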

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

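The test of tandem receptor families and the tests of the kinds of genes on the X, in lists and in families, were chosen after the results they bear on had been seen.

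On sequences outside the 21 main chromosomes, which no comparison used, there were 4 replicated peaks. They are given as values, since called peaks have no counting limit to be set against. They had folds of 3.11 to 3.58, and 3 of them lay on an unlocalized scaffold of chromosome 4.

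Replicate 2 covered more bases than replicate 1. Pooled peaks overlapping replicate 2 alone had a median pooled fold 0.794 times that of peaks overlapping both replicates, and those overlapping replicate 1 alone 0.754 times. The pooled fold is built from both replicates, so peaks missing from either are bound to be weaker, and a difference in sensitivity is neither supported nor excluded. They numbered 58718 for replicate 2 against 16977 for replicate 1. A different cell make-up of the pools stays open: the list farthest from all protein-coding genes, that of GABA and glycine genes, was 0.446 higher in the log2 ratio of covered bases, with a bootstrap interval from -0.12 to 1.75. Read depth and the 2 technical replicates behind replicate 2 may also matter, but depth is not given. No biological explanation other than cell make-up was tested.

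Few X-linked genes were marked. Among members of the constitutive, ribosomal protein and H3K36 lists, 0 of 6 X-linked genes were marked, a share of 0%. Of their autosomal members 78 of 117 were (66.7%, one-sided Fisher exact p = 0.00192). Genes are not independent replicates and were not matched on length here, so the Fisher p-values of this paragraph describe these libraries only. Of the 6, 4 are ribosomal protein genes, which have near-identical pseudogenes, and none is from the H3K36 list; the other 2, against 33 of 43 autosomal genes, are too few (one-sided Fisher exact p = 0.0667). A wider set was the 27 families, grouped by the root of the symbol, that were marked above their random lists, ribosomal protein genes left out. In it, 4 of 47 X-linked members were marked (8.51%), against 673 of 1341 autosomal ones (50.2%, one-sided Fisher exact p = 2.12e-09). The families were chosen by their marked share in these same data, and most members are autosomal. That choice itself raises the 50.2%, and the p is not an unbiased contrast. The X-linked members were, however, also marked less often than all autosomal genes (24.0%). A shared symbol root does not make these members the kinds of genes that carry the mark, and length was not matched. These values therefore cannot decide whether a shortage of such kinds on the X is the whole cause. The median share of exonic 32-base words with a second genomic copy was 0.752 percentage points higher on the X than on the autosomes, but the mean was 23.5% against 9.70%, and 33.0% of X-linked genes had over 10% of such words, against 20.5% of autosomal genes. Reads that cannot be placed may thus lower the share for part of the X. Among genes with at most 10% of such words the ratio of marked shares was still 0.0781, so repeats in exons do not account for the whole difference. Introns were not scanned, although marked is a share of the whole body. Reads that cannot be placed in introns are therefore not excluded as a cause. Replicated peaks on the X had a median fold 0.913 times that on the autosomes (bootstrap interval 0.87 to 0.913). The called peaks that remain on the X were thus somewhat weaker. Places below the limit of calling do not enter, so this ratio cannot tell whether a signal near that limit is the cause. A cell has 1 active X and 2 copies of each autosome, so a lower dose of the mark is a candidate explanation that the design, with both sexes pooled, could not test.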

How the results depend on the processing

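The alternatives for exons in the later part of the body (exons over introns, later over first exons), for replicated peaks with a −log10 q of at least 2, for genes with few repeated words, and for single replicates in gene length and chromosomes were chosen after seeing the data. In replicate overlap, the shares of replicate 1 and replicate 2 peaks were 75.4% and 48.3% with 1 base, 49.99% and 10.3% with 80% of the peak, 74.4% and 18.0% with a −log10 q of at least 2, and 59.97% and 32.6% with lists of equal length. The Jaccard index was 0.232 with the q filter and 0.319 with equal lengths. With the q filter, rho of the folds was 0.277, the share of pooled peaks kept 64.3%, the genic excess 2.16, marked genes 3131 and the ratio of the last to the first 25% of the body 4.74. The genic excess was 2.16 in the replicated list, 2.15 in the pooled list and 2.505 over protein-coding genes alone. A coverage minimum of 20% left 2499 marked genes and moved the length ratio to 54.6. Exons in the later part of the body gave 1.35 over introns. Later over first exons gave 1.501 there, with a different set of first exons. Over the whole body the ratio of later to first exons was 10.5 in the replicated list, 10.6 with the q filter and 11.1 for genes overlapping no other. Beyond 20 kb from a gene 3 intergenic domains were left. By mean in place of median 16 lists stood below the 2.5th percentile, against 0 by median. Many random lists also had a median of 0, and tied lists were given a middle rank. The anterior Hox list, without a peak base, thus stood at the 48.0th and 46.1th percentile by median. A list without coverage could therefore hardly fall below by median. For the other shifts, apart from stricter filters keeping fewer peaks, the cause was not tested. Leaving out a replicate gave 2.148 to 2.1482 for the genic excess, 4922 to 7052 marked genes, 3.96 to 4.47 for position, 1.59 to 1.82 for exons over introns, 9.65 to 9.84 for later over first exons, 4 to 5 lists above the central 95%, 6.58 to 19.8 for the length ratio and 0.075 to 0.164 for the X. Where the main value is the mean of the 2 replicates, a single one always lies within 1 SD of it, and such values are left out of the counts here. The length ratio and the X ratio are not such means, and replicate 2 alone moved both. Otherwise 30 summary values stayed within 1 SD of the replicates, within the 95% interval where there is no SD or, for counts, within 1.5 times. They include the X ratio at 0.0221 with the q filter and 0.115 in the replicated list and the length ratio at 12.4 in the replicated list, which pass only because these ratios differ widely between the replicates. Of the values of single lists and genes, 285 stayed within 1 SD and 80 did not: with the pooled list 24 were higher and 1 lower, with the replicated list 6 higher and 15 lower, 20 were higher as means and 14 lower with the q filter. Values of 0 under every setting, as for the keratinocyte list, could not move. Where the median and its SD were 0, as for the forebrain factors, any mean above 0 counted as moved. These counts are thus partly fixed in advance. No paired analysis was possible because there is a single group. Depth is unknown, so a gene without peaks is not shown to lack the mark.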

Other observations

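The tests in this part were chosen after the data had been seen, apart from those of shared reads and of the last exon, which were written before their results.

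Families of genes grouped by the shared root of their symbols differed widely in how many members were marked. Of 98 families with at least 20 protein-coding genes, 27 stood above and 28 below the central 95% of 1000 random lists matched on length. RNA helicase genes of the Ddx root had 28 of 37 members marked (75.7%, against 29.7% in random lists), led by Ddx17, Ddx39b and Ddx51. RNA polymerase subunits (Polr) had 21 of 28, vesicle sorting genes (Vps) 25 of 35, mitochondrial ribosomal proteins of the large subunit (Mrpl) 32 of 46, translation initiation factors (Eif) 38 of 55, nuclear pore genes (Nup) 14 of 21 and Mediator subunits (Med) 18 of 30. At the other end, 3 of 100 cytochrome P450 and similarly named genes (Cyp) were marked, 0 of 45 collagen and similarly named genes (Col), 0 of 53 keratin genes (Krt), 0 of 23 cadherin genes (Cdh) and 6 of 73 G protein-coupled receptor genes (Gpr). A root of a symbol does not always name a family by descent.

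The 15 marked genes of the X were led by Maged1 at 32.6% ± 18.2 (SD, n = 2), the demethylase gene Kdm5c at 30.5% ± 4.72, the transcriptional coregulator gene Hcfc1 at 29.6% ± 14.7, the filamin gene Flna at 28.3% ± 12.5 and the ubiquitin activating enzyme gene Uba1 at 24.2% ± 18.7. The helicase gene Ddx3x was at 20.8% ± 6.44.

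Zinc finger genes held many of the replicated peaks of highest fold. Of the 20 highest, 11 lay in a gene of the fixed zinc finger list, whose symbols are Zfp and a number (55.0%, 95% Wilson interval 34.2 to 74.2). A further peak lay in Zfp354c, whose symbol is outside that pattern. The list held 24 of the highest 100 and 1594 of all 85758 (1.86%). The highest was in an exon of Zfp27 (chromosome 7, 29893130 to 29896965, fold 8.87), the second in an exon of Zfp605 (chromosome 5, 110127523 to 110129497, fold 8.56) and the third in an exon of Zfp420 (chromosome 7, 29874197 to 29876150, fold 8.24). The share of marked zinc finger genes varied by chromosome, with 56 of 89 on chromosome 7, 16 of 41 on chromosome 17, 9 of 31 on chromosome 13 and 5 of 30 on chromosome 4. Reads shared between exact copies are unlikely to explain it. Of the 32-base words in the 63 zinc finger peaks among the highest 1000, a median of 0.562% had a second copy (mean 1.97%). In the other 937 peaks the median was 0 (mean 1.66%). Copies that differ by a few bases were not counted, and the read length is not given. Peaks called in every tandem family would also mark receptor genes, and 0 olfactory or vomeronasal receptor genes reached 10% in both replicates. The signal was concentrated on the last exon, where the repeated finger domains are usually encoded: the median ratio of coverage of the last exon to that of the rest of the body was 2.55 in 170 marked zinc finger genes, against an upper bound of 1.66 for the central 95% of random lists of other marked genes matched on length. Their last exons are long, with a median of 2714 bases against 1236, which may favour tall peaks. No biological explanation was tested.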
